A study of Homo sapiens with 4 samples.

How the data were processed

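MicroRNA (miRNA) levels were measured on 4 Agilent human miRNA arrays, 2 for the U251 glioblastoma cell line and 2 for the MCF-7 breast carcinoma cell line. The labels call the arrays of each line biological replicates. Per the labels' protocols, cells grew in medium with 10% serum to 60 to 80% confluence, and 100 ng of total RNA was labelled with 1 dye, Cy3. All 4 arrays lay on 1 slide. The U251 pair belonged to one scan and the MCF-7 pair to another, so scan and cell line cannot be told apart, and no block for slide or scan could be fitted.

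Per the file headers, the deposited intensity values came from Agilent Feature Extraction 10.5.1.1, and the submitters' processing notes name Agilent Feature Extraction 10.5. Per the file headers, the array design was annotated against hg18. The deposited processed intensity is a spot's brightness after background subtraction, on a linear scale and not scaled between arrays, so dim spots can be below 0. The deposited files also hold median intensity and local background intensity per spot, a total intensity per miRNA, and other columns, which are flags of 0 or 1 for outlier spots, saturation and signal well above background. The value table of the series equalled the processed intensity spot for spot (largest difference 0). Its medians were 0.589 and 0.224 for U251 and -0.249 and -0.388 for MCF-7. It was linear, not centred and had no direction to settle.

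The arrays carried 12784 spots of 2421 probes for 719 human and 76 virus-encoded miRNAs. Spots with an outlier flag were left out, between 5.71 and 5.90% per array, and no spot was saturated. The processed intensities of a probe's remaining spots were averaged. A probe was called detected on an array where a share of at least 0.5 of these spots was well above background, and a miRNA where any of its probes was. The signal of a miRNA was the sum of its probes' means. Each array was divided by its 75th percentile over the 255 probes detected on all 4 arrays, which was 498 and 564 for U251 and 393 and 387 for MCF-7. Values under 0.0333 of that percentile were set to it. This floor is the highest, over the 4 arrays, of the lowest scaled signal of a detected probe. Log2 was taken last. Signals are therefore relative to the scaling percentile of each array, and values at the floor have no order.

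The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) on the 273 human miRNAs detected on both arrays of at least 1 line, with no covariate. The prior degrees of freedom were 1.12. Where a miRNA was well above background in 1 line and not in the other, its fold is a lower bound, written as at least N-fold. It sets the bright line's mean against the mean, over the other line's arrays, of the higher of the lowest signal among detected probes and the dim probe's own signal, summed over probes. Where this bound fell below equal signal, none is given, and a call then rests on the floor. Values at the floor have no spread of their own, so the adjusted p of such a miRNA rests on the bright line's spread and on the spread shared across miRNAs. With 2 arrays against 2, an exact two-sided permutation test of one miRNA cannot give a p below 0.333, so the p-values depend on limma's pooling of the spread.

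Before the data were examined, 18 miRNA lists were fixed: the miR-200, miR-29 and let-7 families, miR-17~92 with its paralogous clusters, the miR-183/96/182 cluster, luminal breast epithelium, neural and glial, mesenchymal and fibroblast, miR-221/222, regulators of matrix metalloproteinases (MMP) and their inhibitors TIMP and RECK, HOX cluster, methylation-silenced in cancer, the DLK1-DIO3 imprinted cluster, the imprinted cluster C19MC, and markers of blood, muscle, liver and endothelial cells. The 12 lists with at least 3 tested members were tested with camera (limma, preset correlation 0.01), Benjamini-Hochberg adjusted over them. As an alternative, camera estimated the correlation from the arrays, which leaves it only the few degrees of freedom of 4 arrays. Of the miRNAs on lists, 18 belong to more than 1 list. The rule for naming miRNAs was fixed at the same time. It takes, per direction, the 8 largest changes past the threshold among miRNAs detected on all 4 arrays with both arrays of one line above both of the other, and the 8 largest at-least folds among those detected in 1 line. It also takes every member of lists with up to 5 members and the 4 members of longer lists with the largest change among those past the threshold. List members that went against the rest of their list, some list members whose call changed under an alternative, and members of the DLK1-DIO3 list that missed the threshold were named after their values were seen. List members whose bound fell below equal signal, or with a detected probe that did not share the called direction, were also named only then.

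Of the 273 tested miRNAs, 224 were matched to a single gene in a RefSeq table of assembly GRCh38.p14. That build differs from the one in the headers, so the table was used for which miRNA genes neighbour each other (within 10 kb) and no coordinates are given. The steps were tested on simulated data made from the spread of these arrays. Of 273 simulated miRNAs, 92.7% of those changed 2-fold and 100% of those changed 4-fold or 8-fold were called with the right sign, and 3.0% of the calls were unchanged miRNAs. The simulated spread came from miRNAs above the floor on all 4 arrays, with no floor applied and no shift between arrays. These rates therefore do not cover miRNAs at the floor or calls that depend on the scaling. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

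Replicates were compared before averaging. The median squared ratio of their differences to the noise between spots was 2.56 for U251 and 4.48 for MCF-7, against 0.455 for noise alone. Neither pair was within spot noise, which does not show that the cultures were separate, and each array was counted as 1 replicate because the labels call them biological replicates. Other scalings, floors, filters, probe summaries, spread models, detection rules, a replicate block and leaving out each array in turn were tried as alternatives. The planned normexp background correction on mean intensities was not run, because the files used here hold medians and not that column. Normexp on the median intensities was run in its place, first with the deposited backgrounds, and then with backgrounds flagged as outliers set to the array's median, since 1 MCF-7 array had a flagged background of 67590. Called miRNAs with more than 1 detected probe numbered 199, and in 12 of them a detected probe went the other way or showed no difference. The same held for some called miRNAs with 1 detected probe. List members among all of these included miR-138, miR-92b and, in the DLK1-DIO3 list, miR-136*, miR-299-3p, miR-380, miR-539, miR-654-5p and miR-770-5p.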

Results

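The data describe miRNA levels in 2 human cancer cell lines, U251, a line from a glioblastoma (a malignant brain tumour of glial character), and MCF-7, an oestrogen receptor-positive line from a breast carcinoma with luminal epithelial character. The labels describe U251 as migratory and MCF-7 as not migratory, and the title places the series in work on the epigenetic control of pro-invasive genes. Each line was measured on 2 arrays, and this number limits the precision of every value. On the U251 arrays 26.1 and 25.7% of the miRNA spots were well above background, and 246 and 239 human miRNAs were detected. On the MCF-7 arrays 19.4 and 19.1% of the spots were well above background, and 184 human miRNAs were detected on each. Across the tested miRNAs, which are not independent of each other, log2 signals correlated with r = 0.999 between the U251 arrays and 0.995 between the MCF-7 arrays, and with r from 0.527 to 0.551 between arrays of different lines. The SD of the log2 difference between replicates was 0.105 for U251 and 0.270 for MCF-7.

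The comparison asked how the miRNA profile of the migratory line differs from that of the other line. With 1 line of each kind, migration cannot be told apart from tissue of origin or from other traits of the lines. MCF-7 held high signal of the miR-200 family, which represses the mesenchymal transcription factors ZEB1 and ZEB2, and U251 held it at or near background. U251 held miR-221 and miR-222, regulators of the cell cycle inhibitor p27, and most detected miRNAs of the imprinted DLK1-DIO3 cluster, which were not well above background in MCF-7. Of 273 tested human miRNAs, 154 were higher in U251, 87 were higher in MCF-7 and 32 did not pass the threshold (limma, adjusted p under 0.05). With values at the floor used as they stand, estimated changes reached 2-fold for 97 miRNAs higher in U251 and 53 higher in MCF-7. These counts do not use the lower bounds, which were under 2-fold for some of these miRNAs detected in 1 line. The calls were 63.9% higher in U251, and this split depended on the scaling. It was 48.4% with the 75th percentile over all probes, 50.6% after quantile normalization, 44.4% after normexp background correction and 71.8% with no scaling. Of 2421 probes, 471 and 460 were detected on the U251 arrays and 351 and 356 on the MCF-7 arrays. The percentile over all probes therefore lies at mostly undetected probes. Quantile normalization gives 1 distribution to arrays with unlike shares of detected probes. Which scaling lies nearest the true levels was not tested. With the percentile over all probes 91 miRNAs were called higher in U251, and without U251 replicate 1 or replicate 2 the calls higher in MCF-7 numbered 57 or 56. The median log2 change of the tested miRNAs was 0.42 toward U251, so changes near that size depend on the scaling.

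**Figure D1:**
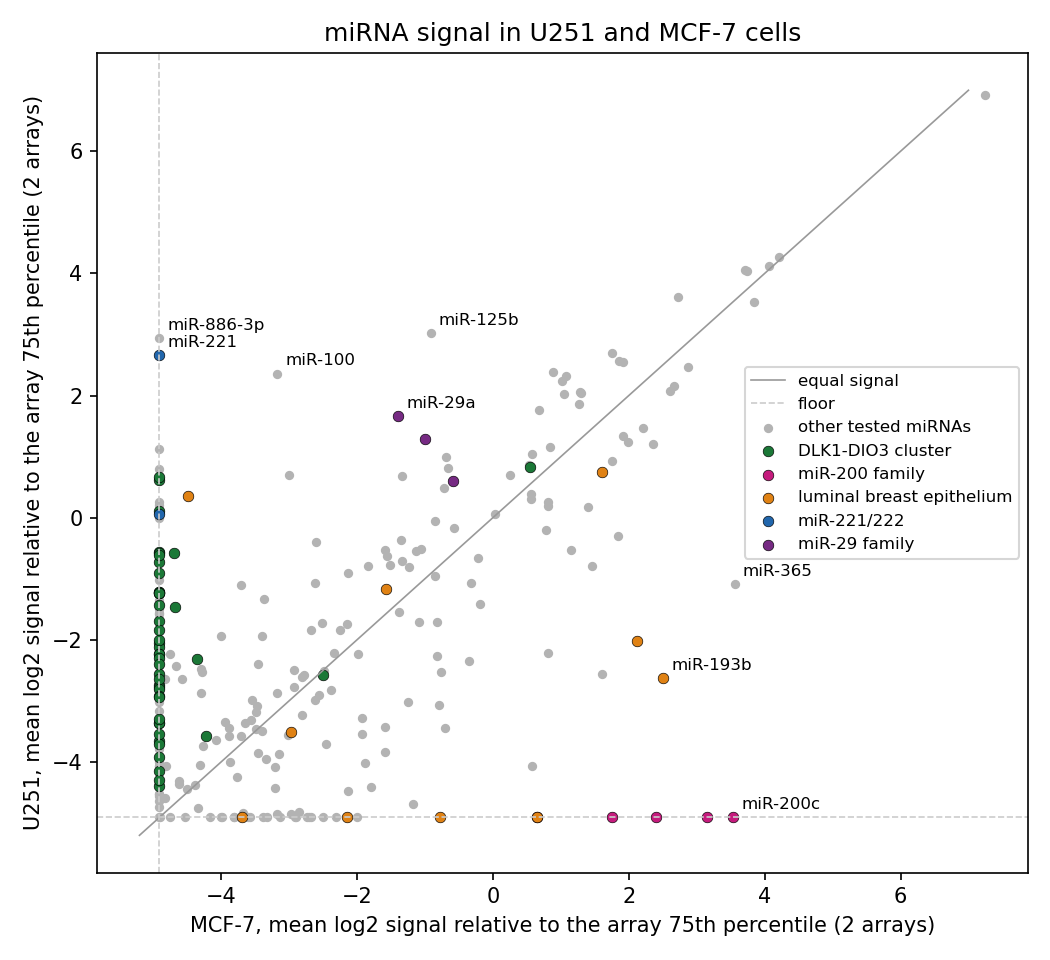
Mean log2 signal of each tested miRNA in MCF-7 (x axis) and U251 (y axis), relative to the 75th percentile of each array over probes detected on all 4 arrays (n = 2 arrays per line). Each point is 1 miRNA, coloured by list, the solid line marks equal signal and dashed lines mark the floor. The miR-200 family lies at the U251 floor, and most of the DLK1-DIO3 cluster and both miR-221 and miR-222 lie at the MCF-7 floor.

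Detection alone separated the lines. On all 4 arrays 140 human miRNAs were detected, 91 were detected on both U251 arrays and neither MCF-7 array, 31 were detected on both MCF-7 arrays and neither U251 array, 26 were detected on other combinations of arrays, and 431 were detected on none. Of the miRNAs detected on all 4 arrays, 64 were higher in U251, 56 were higher in MCF-7 and 20 did not pass the threshold.

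Among miRNAs detected on all 4 arrays, the largest change toward U251 was that of miR-100, which was 46.5-fold higher (log2 change 5.54 ± 0.05 SE, limma adjusted p = 6.69e-06). Its mean log2 signal was 2.36 ± 0.04 in U251 and -3.18 ± 0.06 in MCF-7 (SD, n = 2 each). It was followed by miR-125b (log2 change 3.93), miR-30a (3.69) and miR-29a (3.06). The largest change toward MCF-7 was that of miR-193b, which was 35.2-fold higher there (log2 change -5.14 ± 0.10 SE, limma adjusted p = 4.47e-05). Its mean log2 signal was -2.63 ± 0.16 in U251 and 2.51 ± 0.07 in MCF-7 (SD, n = 2 each). Higher in MCF-7 were also miR-365 and miR-149 (log2 change -4.64 each), miR-7 (-4.17), miR-342-3p (-4.14) and miR-34a (-3.02), a p53 target that restrains the cell cycle. The change of miR-574-3p (log2 change -2.73 ± 0.44 SE) was called with all arrays, and lost its call at a similar size without U251 replicate 1 (-2.89, adjusted p = 0.139) or replicate 2 (-2.57, adjusted p = 0.160). It was also among the miRNAs brighter on MCF-7 replicate 2 than on replicate 1. The array's miR-768-5p, 6.13-fold higher in MCF-7, carries a database version tag in its name.

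Among miRNAs detected only in U251, miR-221 was at least 104-fold higher than in MCF-7, miR-886-3p at least 84.4-fold and miR-130a at least 36.2-fold. These 3 passed the threshold with limma adjusted p from 4.48e-06 to 4.88e-06.

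All 5 members of the miR-200 family were higher in MCF-7. miR-200b was at least 202-fold higher there, miR-141 at least 121-fold, miR-200a at least 76.9-fold and miR-429 at least 35.8-fold, and none of these was well above background in U251. miR-200c was detected on 1 of the 2 U251 arrays, near the lower limit, and was at least 242-fold higher in MCF-7. The family stood apart from the other miRNAs with camera adjusted p = 0.000478, and adjusted p = 0.437 with an estimated correlation. MiRNAs fixed as typical of luminal breast epithelium showed a similar direction, with 8 of 10 tested members higher in MCF-7 (camera adjusted p = 0.0047, and adjusted p = 0.437 with an estimated correlation). They included miR-203, at least 35.8-fold higher, miR-375, at least 13.3-fold higher, and miR-193b and miR-342-3p, given above. The exceptions were miR-135b, which was detected only in U251 and at least 20.8-fold higher there, and miR-148a, 1.33-fold higher in U251, which turned direction with the percentile over all probes and after quantile normalization. miR-135b was brighter on MCF-7 replicate 2 than on replicate 1, and without U251 replicate 1 or 2 its call was lost (adjusted p 0.0634 and 0.0623) while its log2 change stayed at 4.82 and 4.84, against 4.83 with all arrays. miR-191, in this list and higher in MCF-7 (log2 change -0.54, adjusted p = 0.0473), lost its call under several alternatives, among them no scaling (-0.09, adjusted p = 0.569), a replicate block (adjusted p = 0.0614) and leaving out U251 replicate 1 or 2 (adjusted p 0.278 and 0.301), and 7 members were higher in MCF-7 with no scaling. The luminal list's own call was lost over the 140 miRNAs detected on all 4 arrays (adjusted p = 0.148). All 3 members of the miR-183 cluster, at home in epithelia and sensory organs, were higher in MCF-7: miR-183 was 3.99-fold, miR-182 2.70-fold and miR-96 2.32-fold higher. The list did not pass the test (camera adjusted p = 0.073, and adjusted p = 0.437 with an estimated correlation), and miR-182 and miR-183 lost their calls without U251 replicate 1 or 2, with adjusted p from 0.0648 to 0.082. Their log2 changes were then -1.45 and -1.41 for miR-182, against -1.43 with all arrays, and -2.09 and -1.91 for miR-183, against -2.00.

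**Figure D2:**
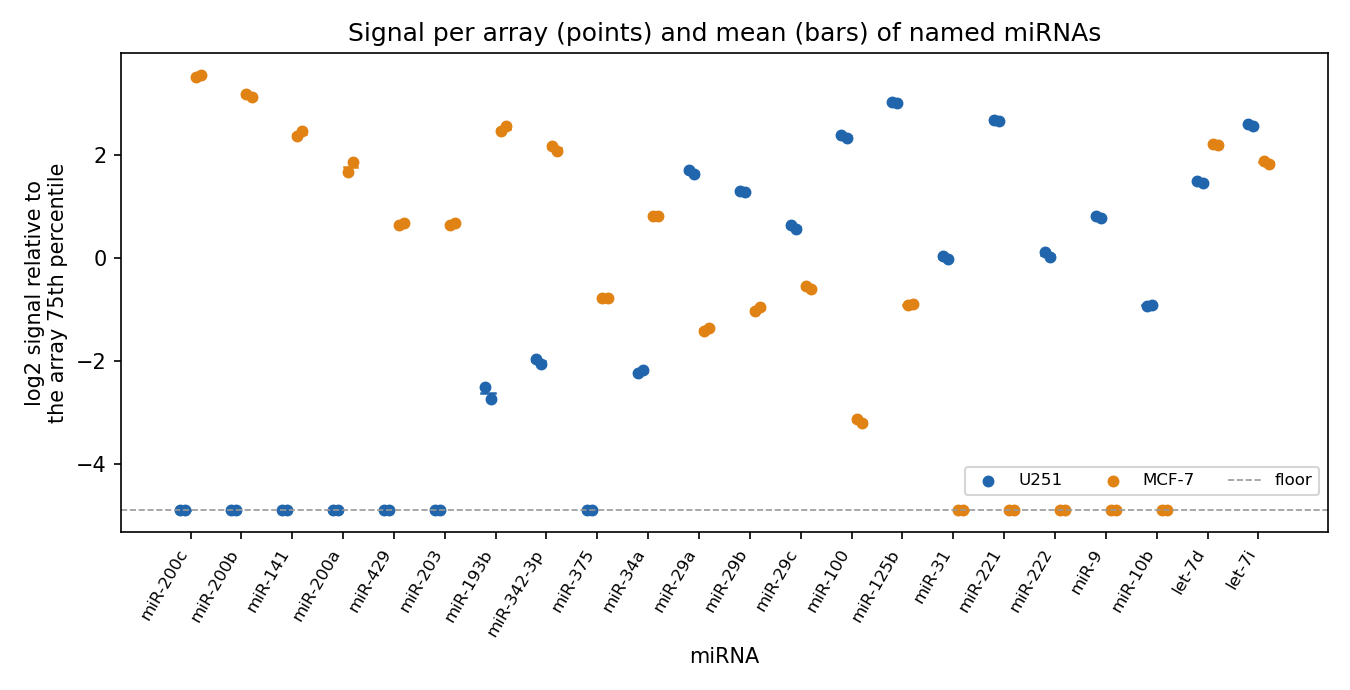
Log2 signal of 22 named miRNAs relative to the 75th percentile of each array, with 1 point per array, bars for the mean of a line (n = 2) and a dashed line for the floor. The arrays of a line lie close together beside the distance between lines, and points at the floor have only an upper bound.

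In U251, 43 of the 46 tested miRNAs of the DLK1-DIO3 cluster, an imprinted region that gives rise to many miRNAs, were higher than in MCF-7, and 42 of the 46 were detected only in U251. Of the 64 members on the array, 18 were detected on no array. miR-376c was at least 26.2-fold higher, miR-376a at least 25.5-fold, miR-377 at least 17.8-fold and miR-127-3p at least 11.2-fold. The median log2 change was 2.64, or 1.67 with undetected members at their bound where they had one. For miR-370, miR-377*, miR-380, miR-411*, miR-654-5p, miR-770-5p and miR-889 the bound fell below equal signal. Their calls rest on the floor, and in both medians their change is the one from the floor. The list stood apart with camera adjusted p = 7.52e-08, and adjusted p = 0.437 with an estimated correlation. The 3 members that did not pass the threshold were miR-494 (log2 change 0.29 ± 0.11 SE), miR-431* (-0.07 ± 0.06) and miR-485-3p (0.65 ± 0.38). No member was called higher in MCF-7, except miR-431* after quantile normalization and after normexp. miR-485-3p was also among the miRNAs brighter on MCF-7 replicate 2 than on replicate 1. By contrast, 0 of the 45 miRNAs of C19MC, an imprinted cluster active in placenta, were detected on any array.

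**Figure D3:**
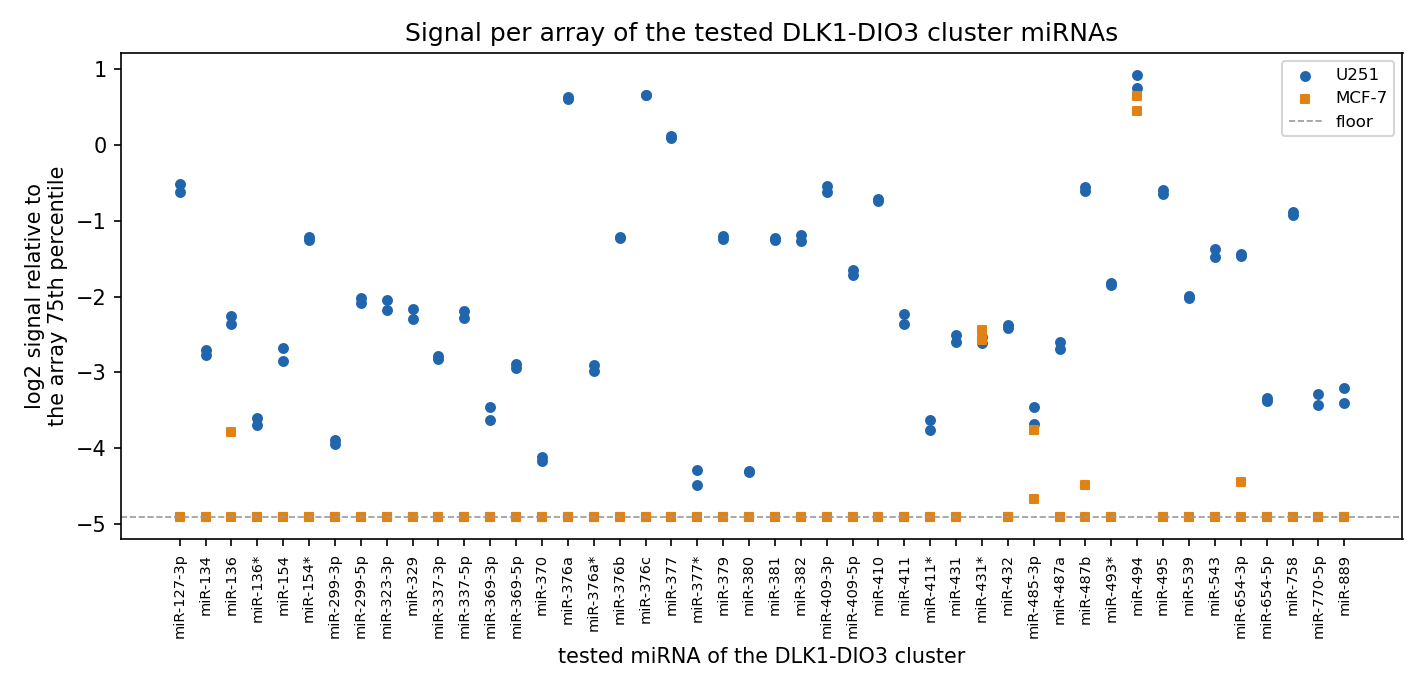
Log2 signal per array of the 46 tested DLK1-DIO3 cluster miRNAs in U251 (circles) and MCF-7 (squares), relative to the 75th percentile of each array, with the floor as a dashed line. MCF-7 points lie at the floor for most members, and miR-494 and miR-431* were detected on all 4 arrays.

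Lists tied to brain, mesenchyme and invasion held members with high U251 signal, without passing the test as lists. The pair miR-221 and miR-222 was detected only in U251, with miR-222 at least 17.3-fold higher. Of the 13 mesenchymal and fibroblast miRNAs on the array, 7 were tested and 6 were higher in U251, among them miR-31, at least 16.5-fold higher, and miR-99a, 4.07-fold higher, beside miR-100 and miR-125b. Only 4 were higher in U251 with the percentile over all probes. In this list miR-152 (log2 change 0.31, adjusted p = 0.0485) turned direction past the threshold after quantile normalization (-0.49, adjusted p = 0.0123) and normexp (-0.23, adjusted p = 0.0239), and miR-21 was 1.25-fold higher in MCF-7, and that call was lost without scaling, where the change turned, and after quantile normalization. Its 6 undetected members were miR-143, miR-145, miR-199a-3p, miR-199a-5p, miR-199b-5p and miR-214 (list camera adjusted p = 0.245, and adjusted p = 0.558 with an estimated correlation). Of the 14 neural and glial miRNAs, 7 were tested, 5 were higher in U251 and 2 in MCF-7. miR-9 was at least 28.7-fold higher in U251, its partner strand miR-9* at least 19.8-fold, and miR-212 and miR-218 were at least 3.07-fold and 3.06-fold higher. miR-7 and miR-128 were higher in MCF-7, the latter 1.84-fold, and the brain miRNAs miR-124, miR-137 and miR-219-5p were not detected (list camera adjusted p = 0.663, and adjusted p = 0.828 with an estimated correlation). Of the 9 tested miRNAs linked to MMP, TIMP and RECK, 6 were higher in U251, among them miR-10b, at least 8.73-fold higher, and 3 (miR-21, miR-15b and miR-16) were higher in MCF-7 by at most 1.33-fold, and without scaling their calls were lost and the changes turned. This list did not pass (camera adjusted p = 0.557, and adjusted p = 0.757 with an estimated correlation) and turned direction over the miRNAs detected on all 4 arrays (adjusted p = 0.853). All 4 tested miRNAs encoded in HOX gene clusters were higher in U251: miR-10a was at least 5.89-fold, miR-196a 4.11-fold and miR-196b 3.51-fold higher, beside miR-10b. The call of miR-196b was lost after normexp (adjusted p = 0.0716), and the list did not pass (camera adjusted p = 0.117, and adjusted p = 0.437 with an estimated correlation). Also in this list, miR-615-5p was not detected and miR-615-3p was not tested.

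The miR-29 family, which targets collagens and the DNA methyltransferases DNMT3A and DNMT3B, was higher in U251 in all 3 members: miR-29a by 8.33-fold, miR-29b by 4.89-fold and miR-29c by 2.27-fold. The family as a list did not pass (camera adjusted p = 0.221, and adjusted p = 0.558 with an estimated correlation), and miR-29c lost its call with the percentile over all probes (adjusted p = 0.0634). MiRNAs known for silencing by promoter methylation in cancers went both ways, in a split that depended on the scaling. Of 14 tested, 6 were higher in U251, 7 were higher in MCF-7 and miR-181c did not pass (log2 change 0.27 ± 0.19 SE). The counts were 4 in U251 and 7 in MCF-7 with the percentile over all probes, and after quantile normalization 4 and 10, where miR-148a, miR-152 and miR-181c were called higher in MCF-7. Those higher in MCF-7 included miR-203, miR-342-3p, miR-34a and miR-34b*, the last at least 5.72-fold, and those higher in U251 included miR-9 and miR-127-3p (list camera adjusted p = 0.245, and adjusted p = 0.757 with an estimated correlation). Of the 13 miRNAs listed for miR-17~92 and its paralogous clusters, which promote proliferation, 10 were higher in U251. Among them miR-363 was at least 6.46-fold, miR-18b 6.09-fold, miR-18a 4.65-fold and miR-19a 3.21-fold higher. The 10 include miR-92b (1.30-fold), which was listed by name and not by gene position and whose call rests on the floor. The 3 members higher in MCF-7 were miR-93 (2.22-fold), miR-25 (1.77-fold) and miR-106b (1.67-fold), which belong to one cluster (list camera adjusted p = 0.36, and adjusted p = 0.828 with an estimated correlation). Of 9 let-7 family members, 6 were higher in U251, 2 were higher in MCF-7 and let-7f did not pass (log2 change 0.05 ± 0.03 SE). These changes were below 2-fold: let-7c (log2 change 0.97), let-7b (1.92-fold) and let-7i (1.64-fold) were higher in U251, and let-7d was 1.67-fold and let-7e 1.49-fold higher in MCF-7. Members called higher in U251 numbered 0 with the percentile over all probes, and let-7a turned direction (log2 change -0.21, against 0.35 in the main version), as did let-7f and miR-98. With no scaling let-7e lost its call (log2 change -0.13, adjusted p = 0.243) and let-7f was called higher in U251, and after quantile normalization let-7f was called higher in MCF-7. Without U251 replicate 1 or 2 the calls of let-7a, let-7b and let-7e were lost at a similar size, with log2 changes of 0.34 and 0.37 for let-7a, 0.92 and 0.96 for let-7b (0.94 with all arrays) and -0.59 and -0.56 for let-7e (-0.57). The let-7 list did not pass (camera adjusted p = 0.663, and adjusted p = 0.861 with an estimated correlation).

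Markers of other cell types were mostly at background. Of the 8 blood cell miRNAs on the array, 7 were not detected, and miR-155, which tumour cells also express, was detected only in U251 and at least 8.12-fold higher there. None of 7 muscle miRNAs was detected, nor was the liver miRNA miR-122. The endothelial miR-126 was 5.05-fold higher in MCF-7 and dim in both lines, with mean log2 signals of -4.47 ± 0.13 in U251 and -2.14 ± 0.04 in MCF-7 (SD, n = 2 each), and miR-126* was not detected.

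Members higher in U251 with the percentile over all probes numbered 40 in the DLK1-DIO3 list, 7 in the miR-17~92 list, 4 in the neural list and 5 in the MMP list, and after quantile normalization 39, 9, 4 and 5. Outside the DLK1-DIO3 list, the bound also fell below equal signal for miR-138 (neural), miR-146a (MMP), miR-92b (miR-17~92) and miR-193a-5p (luminal), whose calls rest on the floor. Adjusted over the list alone, every list with a tested member gave the same counts of calls as over all tested miRNAs. Camera called 3 of the 12 tested lists with its preset correlation and 0 with an estimated correlation, where the smallest unadjusted p was 0.0924. The estimated version has few degrees of freedom, so few lists could pass it. Its camera p rose also where the estimated correlation lay under the preset 0.01. It went from 0.0243 to 0.149 for miR-183 (correlation -0.28), from 0.0487 to 0.182 for HOX (-0.0095) and from 0.464 to 0.526 for MMP (-0.10). The lost calls therefore cannot be ascribed to correlation between members alone. fry, which asks if a list's members move one way and compares them with no other miRNA, called 12 of 12. Each line was scanned apart from the other, so no model of these arrays could take scan into account. With normexp and flagged backgrounds left as deposited, 0 miRNAs passed the threshold with limma and 13 had an unadjusted p under 0.05.

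Probes for virus-encoded miRNAs served as a background. Of 76, 2 were detected on each U251 array, 5 on MCF-7 replicate 1 and 6 on MCF-7 replicate 2. This background differed between the lines. Mean log2 signal was 0.28 in U251 and -1.46 in MCF-7 for ebv-miR-BART13, and -1.89 and -3.23 for kshv-miR-K12-3. Higher in MCF-7 were ebv-miR-BART12, ebv-miR-BART16, ebv-miR-BART20-5p and kshv-miR-K12-12, which lay at or near the floor in U251.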

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

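Of the tests in this part, that of the brighter U251 arrays and that of noise between spots were chosen before their results were seen, and the others only after.

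Signals of 6 virus-encoded miRNAs were picked out because they lay outside the main measurement and were detected above the negative controls, whose 99th percentile was 6.76 to 7.79 on the 4 arrays. The highest probe signal over the arrays was 531 for ebv-miR-BART13, 108 for kshv-miR-K12-3, 38.4 for kshv-miR-K12-12, 24.3 for ebv-miR-BART12, 21.6 for ebv-miR-BART16 and 15.6 for ebv-miR-BART20-5p. BART13 and K12-3 were detected on all 4 arrays, BART12, BART16 and K12-12 on both MCF-7 arrays, and BART20-5p on 1 MCF-7 array.

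On MCF-7 replicate 2, 17 tested miRNAs were at least 0.5 log2 brighter than on replicate 1, with a median difference of 0.998, and 0 were dimmer by as much. Before scaling, the median difference over 175 miRNAs detected on both MCF-7 arrays was 0.0472 (quartiles -0.028 and 0.160), against 0.975 for the set, which argues against a difference in overall brightness. The count of 0 and the 34 probes of the set, all of which (100%) differed by more than noise between spots allows, compare 1 array with 1 array on miRNAs that are not independent or were picked for their difference, so they decide nothing about noise. Of 6 virus-encoded miRNAs detected on an MCF-7 array, BART12, BART16, BART20-5p and K12-12 were over 0.5 brighter on replicate 2 and BART13 (0.0811) and K12-3 (0.098) were not, with a median of 0.718, or 0.677 over the 5 detected on both MCF-7 arrays, so labelled RNA binding to probes other than the intended one is a candidate explanation for part of the set. A difference between the cultures stays open and untested, and without this set 152 miRNAs were called higher in U251 and 78 higher in MCF-7.

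More human miRNAs were detected on the U251 arrays (246 and 239) than on the MCF-7 arrays (184 on each). With 1 signal limit for all arrays the mean counts were 243.5 and 188.5, and after dimming the U251 arrays to the MCF-7 level the U251 mean was 216.5 (221 and 212, with the higher MCF-7 count at 195). This mean lies above the bound of 214.5 set beforehand, which counts against brightness as the whole cause, but by less than the spread of the U251 counts. That the excess must pass the spread was asked only after the result was seen, and on that reading brightness and a real difference cannot be told apart. Without the DLK1-DIO3 cluster the means were 196.5 for U251 and 181 for MCF-7, within the 10 percent that was set, so the cluster may account for most of the gap, although both U251 counts (200 and 193) stayed above both MCF-7 counts.

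The DLK1-DIO3 cluster miRNAs were detected in U251 and mostly not in MCF-7. A shared scan or slide position would shift other miRNAs of like signal too, yet 138 others detected on both U251 arrays within the cluster's range of U251 signal had a median log2 change of 0.429, with an upper quartile of 1.47, against 2.64 for all 46 tested cluster miRNAs, whose lower quartile was 1.56 (medians before scaling 0.871 and 3.10). Signal carried over between probes of members with near-identical names would leave only such members, and 34 members outside the miR-376 subfamily and the miR-154 subfamily with its relatives were detected on both U251 arrays. Similarity was set by name alone, since no probe sequences were given, so signal carried over between probes of other names stays open. Activity of the imprinted region in U251 and not in MCF-7 remains a hypothesis, since it was found and tested on the same data, and the cluster's methylation was not measured in the files used here.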

How the results depend on the processing

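The normexp versions, the crossed replicate block and the version without the miRNAs brighter on MCF-7 replicate 2 were chosen after seeing the data. The planned normexp on mean intensities and the slide block were not run. The miR-200 call was kept under all alternatives except an estimated correlation, that of the DLK1-DIO3 list under all except that and normexp with flagged backgrounds kept, and that of the luminal list under all except those and the filter on all 4 arrays. The filter on all 4 arrays left fewer than 3 members of the miR-200, DLK1-DIO3, HOX and neural lists and gave no value for them. Signal over background limits what can be said of dim miRNAs, and the folds of those detected on all 4 arrays, such as miR-126, miR-196b and miR-768-5p, are not bounds.

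The 241 calls (154 higher in U251, 87 in MCF-7) became 123 (67 and 56) over the 140 miRNAs detected on all 4 arrays, where fewer were tested. At an estimated 2-fold or more, with values at the floor used as they stand, 150 calls (97 and 53) were left. With the percentile over all probes 91 were higher in U251 and with normexp 100, where the median log2 change moved by -0.46 and -0.57. With quantile normalization it moved by -0.42 and with no scaling by 0.44. Leaving out 1 array gave 183 to 231 calls, 126 to 144 higher in U251 and 56 to 90 higher in MCF-7, where 57 and 56 were without U251 replicates 1 and 2. The lone array of a line was assumed to vary like the other line. The labels give both lines replicates 1 and 2, and same-numbered arrays deviated with r = -0.22. A replicate block gave 151 and 87 calls and changed no list's call, and the crossed block gave 158 and 92.

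With normexp and flagged backgrounds kept there were 0 calls (0 in either direction). The lower quartile of the probes was then 988 on MCF-7 replicate 1 against 57.2 with those backgrounds replaced, and the replacement was made after this result was seen. In that version the DLK1-DIO3 (adjusted p 0.747), HOX (0.763) and neural (0.747) lists turned direction, the luminal list lost its call (0.0769), and the miR-29 (0.000844), let-7 (7.55e-06), miR-17~92 (0.0103), mesenchymal (6.19e-06) and MMP (0.00158) lists gained one. There the log2 changes of miR-10a (-0.68), miR-10b (-0.60), miR-127-3p (-0.35), miR-155 (-0.62), miR-18a (-0.22) and miR-18b (-0.75) turned direction. Those of miR-196a (-0.69), miR-196b (-0.69), miR-212 (-0.69), miR-218 (-0.68) and miR-363 (-0.68) turned too, and none of all these passed the threshold. The median log2 change of the 273 tested miRNAs was -0.686 in that version, so most of these values lie near the shift of all tested miRNAs.

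With an estimated correlation, a version with few degrees of freedom, the miR-200, luminal and DLK1-DIO3 lists each had a camera adjusted p of 0.437. The luminal list lost its call over miRNAs detected on all 4 arrays (0.148), where 4 of its members higher in MCF-7 are left out. The let-7 list turned direction with the percentile over all probes (0.565) and without U251 replicate 2 (0.966; 0.425 to 0.997 over the arrays left out), and the MMP list over miRNAs detected on all 4 arrays (0.853), none past the threshold. Calls were gained with normexp by the miR-29 (0.0193), mesenchymal (0.00386) and MMP (0.0276) lists, with no filter by the miR-29 (0.00978), miR-17~92 (0.00978) and miR-183 (0.00978) and HOX (0.0123) lists, with each probe tested by itself by the miR-29 (0.0367), miR-183 (0.00102) and HOX (0.0121) lists, and with no scaling by the miR-183 list (0.036). fry called the miR-29 (0.000285), let-7 (0.0194), miR-17~92 (0.000441), miR-183 (0.000441), neural (0.000451), mesenchymal (7.57e-05), MMP (3.72e-05), HOX (7.57e-05) and methylation-silenced (0.0102) lists, which camera did not. The mean correlation between lines was 0.720 over all human miRNAs, which adds undetected ones at the floor. For the miRNAs that the rule fixed beforehand names, 1276 values under the alternatives kept their call and direction, 59 lost the call and 11 turned, all of these 11 with flagged backgrounds kept. That rule favours large changes, so these numbers do not describe smaller ones. Among all calls shared with the main version, 15 of 200 had the other direction with normexp and replaced backgrounds. It was 7 of 210 after quantile normalization and 1 of 221 with no scaling. Apart from constructions named here, the cause was not tested.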

Other observations

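Tests in this part were all chosen after the results were seen, as were the miRNAs it names. MiRNA genes within 10 kb of each other formed 25 clusters of tested hairpins, some of them on the fixed lists. Among pairs on none of the lists, both hairpins of the miR-195 and miR-497 pair were higher in MCF-7, with log2 changes from -2.00 to -1.84. The miR-301b and miR-130b pair was higher in U251, from 1.22 to 2.06, as was the miR-23b and miR-27b pair, from 0.75 to 1.09. Some other pairs on none of the lists did not change alike. The log2 changes were 1.46 for miR-939 and -0.37 for miR-1234, and 3.35 for miR-224 and 0.16 for miR-452. Further such pairs shared a sign. The log2 changes were -1.21 for miR-421 and -0.439 for miR-374b, 0.635 for miR-27a and 0.28 for miR-23a, and 0.305 for miR-30b and 0.0391 for miR-30d. With the percentile over all probes miR-130b, miR-23b and miR-27b lost their calls, and miR-301b lost its call after normexp.

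Shared transcription of neighbouring miRNA genes is a hypothesis for like changes within a cluster. Without the DLK1-DIO3 cluster, 96.1% of the variance of log2 changes of 56 hairpins lay between 23 clusters, against a median of 39.3% and a 95th percentile of 55.9% over 10000 random reassignments of hairpins to clusters (permutation p = 1e-04, the smallest they can give). The miR-200b (-6.66 to -5.33), miR-200c (-8.44 to -7.32) and miR-221 (4.97 to 5.18) clusters have the largest changes and weigh most in this share. The share without them was not computed. In 20 of these 23 clusters all hairpins had changes of one sign. That count has no random rate beside it and includes small changes, such as 0.0391 for miR-30d and 0.13 for miR-181d. Similar sequences within a family may add to like changes within a cluster, and that was not separated.

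Changes of the 2 arms of a hairpin also correlated across hairpins, as they would if one precursor gives both. Across 50 hairpins with 2 tested arms, Pearson's r of the arms' log2 changes was 0.782 and Spearman's rho 0.869 (permutation p = 1e-04 for each, the smallest 10000 permutations can give), and 43 of 50 had the same sign. Without the DLK1-DIO3 cluster r was 0.817 over 39 hairpins, and without the 2 hairpins farthest from the median it was 0.790. Within a hairpin the sizes could differ, as for miR-377 and miR-377* (5.02 and 0.52) and for miR-32 and miR-32* (-0.49 and -3.52). No random rate was computed for the 43 of 50. Hairpins are not independent replicates.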
